A study of Mus musculus with 24 samples.

How the data were processed

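Lateral septum tissue of male C57BL/6J mice was profiled by directional, poly(A)-selected RNA sequencing of RNA extracted with TRIzol, read as 150 bp pairs on an Illumina instrument, per the labels. The 24 libraries fall into 8 groups of 3: mice after 1, 4, 7 or 10 days of chronic social defeat stress (CSDS) and age-matched unstressed controls for each of these days. The submitters' processing notes name fastp, HISAT2 and HTSeq, without versions, and the mouse build GRCm39. The authors deposited a table of read counts per gene and a table of FPKM per gene, each with 24 columns of per-sample values and 28859 genes. The deposited counts are whole numbers. For the 27139 genes with counts in at least 2 libraries, the deposited FPKM equal the count divided by the column total and by 1 length per gene that is the same in every library. The reference annotation at hand was of an older build and was used only for gene names and gene order.

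Total counts ran from 31182700 to 41205400 per library, with a median of 38196600. Among the more highly expressed genes, the median standard error of a log2 fold change between stressed and control libraries of a single day was between 0.0927 and 0.0930. That of the average over the 4 days was 0.0465 among the same genes. Genes with lower counts were left out of these medians. Intervals on shares of counts are 95% Wilson intervals and cover counting error only.

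Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 18060 genes, and libraries were scaled by TMM. One quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to the 8 group means, with 16 residual degrees of freedom and a prior of 5.14. The comparisons were CSDS minus control on each day, the mean of the 4 daily differences, an F test of whether the response to CSDS differed between days, and F tests of differences between days among controls and among stressed mice. The response on day 10 minus that on day 1 was added for single genes and lists after the data had been seen. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, and an adjusted p under 0.05 was called. Standard errors (SE) were the absolute log2 fold change divided by the square root of F. CPM are edgeR's cpm values after TMM. The p-values measure differences between libraries. The labels speak of mice but do not say in so many words that each library is a separate animal.

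Genes called on more than 1 day were counted for the 6 pairs of days, in each direction, with Fisher's exact test and Benjamini-Hochberg adjustment. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, and again with a correlation estimated per list. The adjustment ran over the 32 lists. Within a list, p-values of single genes were also adjusted over the list alone. The lists covered ER chaperones with ER-associated degradation, the integrated stress response, ER to Golgi transport, ER calcium handling, immediate early genes, glucocorticoid-responsive genes, cytosolic heat shock genes, the circadian clock, nuclear oxidative phosphorylation genes, cytosolic ribosomal proteins, the proteasome, cholesterol synthesis, mitochondrially encoded genes, interferon response, inflammation, glutamate and GABA synapses, and neuropeptides with stress receptors. Further lists held markers of lateral septum neurons, striatum, medial septum, cortex or hippocampus, thalamus or hypothalamus, choroid plexus, ependyma, myelin, oligodendrocyte precursors, astrocytes, microglia, endothelium, mural and leptomeningeal cells, blood cells and newborn neurons. Of 930 list entries, 895 matched a symbol as written, 20 matched by a synonym, 13 were mitochondrial genes and 2 did not match.

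Groups, tests, lists, other ways of analysis and the rule for naming genes were fixed before the data were examined. The rule named up to 10 rising and 10 falling called genes per comparison by size of fold change. They needed a mean of at least 1 CPM in the higher group, no overlap between the 3 stressed and 3 control libraries, which chance gives in a share of 0.1 (or the same direction on all 4 days for the average), and an established symbol. With fewer than 3 such genes, the 5 genes with the smallest p were named. For the F tests, 10 genes with the smallest p were named. Up to 4 called members of each list and 11 fixed genes, Manf among them, were named in every comparison. Genes named outside this rule were chosen after their values were seen.

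The other ways of analysis, set beforehand, were RLE size factors, DESeq2 1.42.0, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries), the replicate number as a block, 1 surrogate variable from sva 3.50.0, limma on log2 FPKM with a pseudocount of 1 or 0.1 for genes with at least 0.5 FPKM in 3 libraries, libraries of the compared day alone, each library left out in turn, the estimated correlation for lists, and overlaps at an unadjusted p under 0.01. Choroid plexus and cortex marker scores as covariates were added after the data had been seen. A marker score is the mean log2 CPM of a list in a library. Gene length was taken from the ratio of count to FPKM, and each library's trend with it was removed by lowess in a check also added after the data had been seen. Replicate numbers did not pair libraries: 2 of 12 stressed libraries correlated above 0.1 with the control of the same number, and the values ran from -0.42 to 0.18. The fit with the replicate number is therefore given only as an alternative. Other splits of the libraries were all 10 splits of a day's 6 libraries, or 100 drawn regroupings.

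The procedure was tested on simulated data with 200 changed genes and the sample layout and per-gene spread of these libraries. Genes were drawn independently, each around 1 mean, without differences between days or shared RNA of neighbouring tissue. The numbers of false calls below therefore may not carry over to the real libraries. On a single day the edgeR test recovered 41.8% of genes with a planted 1.5-fold change, 68.7% at 2-fold and 77.3% at 4-fold, with 4 false calls. For the average of 4 days it recovered 76.1%, 87.9% and 96.9%, with 8 false calls. DESeq2 made between 17 and 51 false calls in simulations with planted changes, where edgeR made between 1 and 10. No per-sample column was left out. Outliers within groups were not tested, since groups of 3 are too small. Reads were not used here.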

Results

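Gene expression was measured in the lateral septum, a forebrain region, of male mice after 1, 4, 7 or 10 days of CSDS, in which an aggressive CD-1 male confronts the mouse for 10 min a day and then stays nearby behind a barrier. Age-matched unstressed controls stood beside each day. There were 12 stressed and 12 control libraries, 3 per group, with total counts between 31182700 and 41205400. The series title places the study around MANF, a secreted protein of the endoplasmic reticulum (ER), and ER function under CSDS. Of 28859 genes in the count table, 18060 were tested.

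The libraries differed in how much RNA of neighbouring tissue they held. Ttr, the thyroid hormone carrier made by the choroid plexus, ran from 5.01 to 8945 CPM over the 24 libraries. Its group mean was 153 ± 247 CPM in day 1 controls and 2677 ± 4301 in day 1 stressed mice (SD, n = 3), and 5954 ± 3112 against 2119 ± 3618 on day 10. Days 4 and 7 had means of 2836 ± 2922 and 1038 ± 1782 CPM in controls and 1072 ± 1810 and 1783 ± 1380 in stressed mice. Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, ran from 15.9 to 524 CPM. Choroid plexus markers had a median log2 fold change (CSDS minus control) of 2.98 on day 1, -1.28 on day 4, 0.72 on day 7 and -1.44 on day 10, and none of these 4 sets of 20 genes kept its camera call with an estimated correlation (adjusted p = 0.795, 0.944, 0.750 and 0.730 with an estimated correlation). In day 10 control replicate 1, the unnamed locus LOC118568312 took 6.03% of the counts (95% interval 6.02 to 6.04), against at most 0.0939% (0.0929 to 0.0949) in any other library. That library also had the lowest total count (31182700), the fewest genes detected (21521) and the lowest TMM factor (0.947) of the 24. Its share of mitochondrial counts was the lowest too, at 3.28%. Whether the RNA or the preparation of that library differed was not tested. The first 3 principal components held 22.5%, 14.9% and 10.8% of the variance.

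Manf (Entrez 74840), the gene in the series title, did not pass the test on any day. Its log2 fold change in stressed mice was 0.42 on day 1 (SE 0.17, adjusted p = 0.601), -0.34 on day 4 (adjusted p = 0.622), -0.34 on day 7 (adjusted p = 0.999) and -0.68 on day 10 (SE 0.17, adjusted p = 0.109). Mean levels were 49.6 ± 3.3 CPM in controls and 66.5 ± 11.7 in stressed mice on day 1, and 70.2 ± 26.6 against 43.6 ± 3.7 on day 10 (SD, n = 3). Over the ER chaperone list alone, Manf was lower on day 10 with an adjusted p of 0.00326. Its paralog Cdnf was higher on day 10 over the list alone by 0.79 (SE 0.29), with an adjusted p of 0.276 over all genes. The test of a difference in response between days gave Manf an adjusted p of 0.177. The response on day 10 minus that on day 1, a comparison chosen after seeing the data, was -1.11 for Manf (adjusted p = 0.0400), and -0.84 (adjusted p = 0.331) with the choroid plexus and cortex scores as covariates. That call stayed in 5 of 12 runs with 1 library of these days left out: it was lost without day 1 control replicates 1, 2 or 3, day 1 CSDS replicate 1, day 10 control replicate 2 or day 10 CSDS replicates 1 or 3 (adjusted p of up to 0.123). Without day 10 control replicate 1, where Manf stood at 99.4 CPM, its day 10 log2 fold change was -0.36 (adjusted p = 0.341).

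**Figure D1:**
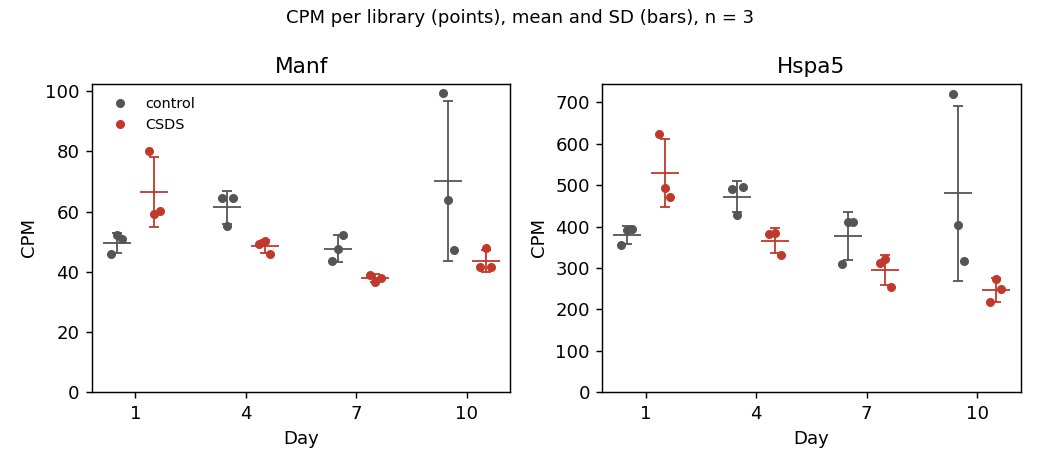
CPM of Manf and Hspa5 in each library (points) by day, with the mean and SD of each group of 3 (bars); controls are grey and stressed mice red. Day 10 control replicate 1 had the highest level of both genes, 99.4 CPM for Manf and 720 for Hspa5.

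On day 1, activity-dependent immediate early genes were lower in stressed mice than in the controls of that day. Egr2, a transcription factor of this class, was the only gene called: it fell by 1.60 on the log2 scale (SE 0.24, adjusted p = 0.0209, edgeR quasi-likelihood), from 13.1 ± 3.4 to 4.32 ± 0.48 CPM (SD, n = 3). Of 35 immediate early genes, 33 had lower values, with a median log2 fold change of -0.48, 20 were lower when adjusted over the list alone, and the list's call held with an estimated correlation (adjusted p = 0.0446). Cortex and hippocampus neuron markers lay lower in the same stressed group, with 15 of 23 values below 0 and a median of -0.23 (adjusted p = 0.646 with an estimated correlation), and Slc17a7 stood at 34.0 CPM in CSDS replicate 3 against 178 to 524 in the other day 1 libraries. With the choroid plexus and cortex scores as covariates (chosen after seeing the data), 27 of 35 immediate early genes had lower values and 13 were lower over the list alone, against 9 without CSDS replicate 3 and 11 without control replicate 2. Values that did not pass over all genes were -1.43 for Fos and -0.61 for Egr1, with 1.24 for Nat8f3 and 0.44 for Hdac4 (all adjusted p = 0.226). Junb, Nr4a1 and Arc, called over the list alone, had values of -0.93, -0.86 and -0.63. Egr2 stood at 9.30 to 15.9 CPM in day 1 controls, 3.93 to 4.85 in day 1 stressed libraries and 2.61 to 6.24 in later controls. Fos stood at 33.1 to 56.3, 13.1 to 19.3 and 6.77 to 26.6 CPM in the same groups. The list's score was 4.65 to 4.95, 3.90 to 4.49 and at most 4.15 in them. High day 1 controls and a fall under stress therefore cannot be told apart, since days also differ in age and any batch. At an unadjusted p under 0.05 there were 1423 genes. The Egr2 call stayed only without control replicate 3. It was lost without each of control replicates 1 and 2 and CSDS replicates 1, 2 and 3, with adjusted p between 0.00676 and 0.317 over the 6 runs. With the covariates Egr2 stood at -1.58 (adjusted p = 0.0535) and edgeR called 0 genes (995 at an unadjusted p under 0.05), and DESeq2 called 15 without them.

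Genes of the ER chaperone list lay higher on day 1: 33 of 46 had values above 0 (median 0.11), and none was called over all genes. Adjusted over the list alone, 4 were higher: Sdf2l1 by 0.81, Creld2 by 0.56, Herpud1 by 0.33 and Syvn1 by 0.25. The list's call was lost with an estimated correlation (adjusted p = 0.368 with an estimated correlation). Hspa5, the main ER chaperone (BiP), stood at 0.48 (adjusted p = 0.608), and Xbp1 at 0.31 (adjusted p = 0.566). Cholesterol synthesis genes lay lower, with 22 of 24 below 0 and 7 lower over the list alone. Among these, Insig1 stood at -0.35 (list adjusted p = 0.330 with an estimated correlation). Heat shock genes had 17 of 23 values above 0 (median 0.10; list adjusted p = 9.1e-04, and 0.795 with an estimated correlation), a call also lost without control replicate 1 (adjusted p = 0.104). All 13 mitochondrially encoded genes had lower values, with a median of -0.26 (adjusted p = 0.368 with an estimated correlation). Fkbp5, a glucocorticoid target, stood at 0.40 (adjusted p = 0.323), Tsc22d3 at 0.13, Atf4 at -0.06, Ddit3 at 0.13 and Npas4 at -0.36. Choroid plexus markers were higher in the same stressed group, with a median of 2.98, and CSDS replicate 1 held 7639 CPM of Ttr.

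By day 4, 20 genes were called, of which 9 rose and 11 fell in stressed mice (1505 at an unadjusted p under 0.05). Among those that fell were 4 of the 23 genes of the heat shock list, whose own call was lost with an estimated correlation (adjusted p = 0.191 with an estimated correlation). Dnajb1, a co-chaperone of Hsp70, fell by 0.91 on the log2 scale (SE 0.09, adjusted p = 2.8e-05), from 117 ± 16 to 62.3 ± 5.8 CPM (SD, n = 3). The small heat shock protein Hspb1 fell by 1.26 (SE 0.23, adjusted p = 0.0186). The inducible Hsp70 genes Hspa1a and Hspa1b fell by 2.17 and 2.19, although these paralogs share reads, so which of the pair changed is uncertain. Day 4 controls held 13.4 to 38.5 CPM of Hspa1a and 15.8 to 49.4 of Hspa1b. Controls of the other days held 4.95 to 14.4 and 5.63 to 19.2, and stressed day 4 libraries 4.31 to 6.81 and 5.23 to 7.84. Egr1 fell by 0.74 (adjusted p = 0.00684). Stressed day 4 libraries held 58.6 to 69.0 CPM of Dnajb1. Controls held 104 to 134 on that day, 92.1 to 104 on day 1 and 52.3 to 64.3 on days 7 and 10. For Egr1 these ranges were 129 to 148, 219 to 242, 294 to 365 and 119 to 166 CPM. A fall under stress and a difference between control days therefore cannot be told apart for Dnajb1 and Egr1. Hspb1, at 4.02 to 5.71 CPM in stressed day 4 libraries, lay below every control (at least 6.08). Further genes that fell were Bcl6b (-1.31), Ccdc117 (-0.75), Apold1, an endothelial early response gene (-0.74), Spry4, a feedback inhibitor of receptor tyrosine kinase signalling (-0.66), Jmjd6 (-0.41) and Cst3, cystatin C (-0.40).

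Among the genes that rose on day 4, Lrg1, a secreted glycoprotein, had the largest fold, 4.08 on the log2 scale (SE 0.57, adjusted p = 0.00273), at a low level of 0.0941 ± 0.0382 CPM in controls and 1.65 ± 0.17 in stressed mice. Vwf, the clotting factor carrier of endothelium, rose by 1.25 (SE 0.22, adjusted p = 0.0154). The transferrin receptor Tfrc rose by 0.57 (SE 0.09, adjusted p = 0.00929), from 92.2 ± 11.9 to 137 ± 8 CPM. Others were Fam214a (0.59), the sialomucin Podxl (0.59), the chemokine Cxcl12 (0.54), Marchf7 (0.46), the taurine transporter Slc6a6 (0.43) and the splicing factor Srsf5 (0.36). Stressed day 4 libraries held 55.6 to 57.2 CPM of Fam214a, 57.9 to 60.9 of Marchf7 and 200 to 214 of Srsf5. Day 7 controls held 46.8 to 56.9, 56.4 to 58.3 and 198 to 216, so these ranges overlapped. Lrg1 and Vwf in stressed day 4 libraries lay above every control library (at least 1.51 and 33.2 CPM, against at most 0.907 and 28.9). Among the heat shock list, 22 of 23 genes had lower values on day 4 (median -0.25), 4 were called, and 14 were lower when adjusted over the list alone (list adjusted p = 1.2e-21, and 0.191 with an estimated correlation). Immediate early genes had 28 of 35 lower values and 14 called over the list alone (adjusted p = 0.191 with an estimated correlation). For nuclear oxidative phosphorylation genes 71 of 74 values were lower, by a median of -0.14 (adjusted p = 0.312 with an estimated correlation). Across genes, day 4 log2 fold changes were higher for longer genes (Spearman rho = 0.19, against 0.026, -0.024 and 0.075 on days 1, 7 and 10 and 0.14 on average). With each library's trend with gene length removed (chosen after seeing the data), the day 4 oxidative phosphorylation score differed by -0.0713 (95% interval -0.136 to -0.00672), against -0.136 (-0.260 to -0.0126) before. Endothelial markers had 16 of 20 values above 0 (adjusted p = 0.308 with an estimated correlation), and choroid plexus markers a median of -1.28. The blood cell score was also higher, at 0.519 to 1.34 in stressed day 4 libraries and -1.31 to -0.106 in controls. That list was called with the preset correlation and lost with an estimated one.

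Not passing on day 4 were Hspa5 (-0.37, adjusted p = 0.665), Sdf2l1 (-0.57), Creld2 (-0.35), Xbp1 (-0.10), Atf4 (-0.22), Ddit3 (-0.20), Fkbp5 (0.20), Tsc22d3 (-0.20), Npas4 (0.16) and Fos (-1.19, adjusted p = 0.159). The ER chaperone list lay lower, with 34 of 46 values below 0 (adjusted p = 0.00523, and 0.794 with an estimated correlation). That call was also lost without control replicate 1 (adjusted p = 0.0587). The number of genes called was 10 without control replicate 1, 6 without control replicate 3, 3 without CSDS replicate 2 and 9 without CSDS replicate 3. Dnajb1, Fam214a and Lrg1 stayed called whichever day 4 library was left out, whereas Hspa1a was lost without CSDS replicate 2 (adjusted p = 0.0683). Tfrc was lost without control replicate 3, CSDS replicate 2 or CSDS replicate 3, and Hspb1 without control replicates 1 and 3 or CSDS replicates 1 and 2, with adjusted p of up to 0.0723 and 0.187. Egr1 was lost without CSDS replicates 2 or 3 (up to 0.0683) and Cxcl12 without control replicate 3 or CSDS replicate 2 (up to 0.0637). Hspa1b, Bcl6b, Jmjd6 and Marchf7 stayed called only without control replicate 2 (adjusted p of up to 0.169, 0.327, 0.155 and 0.199 in the other runs), and Apold1, Slc6a6 and Vwf only without CSDS replicate 1 (up to 0.404, 0.150 and 0.154). Ccdc117, Podxl, Spry4, Srsf5 and Cst3 stayed called in 2 of 6 runs each.

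Day 7 brought a single called gene, Tfrc, which rose by 0.58 on the log2 scale (SE 0.09, adjusted p = 0.0495), from 106 ± 2 to 159 ± 5 CPM (SD, n = 3). Next by p, without passing, were Hnrnpdl, an RNA-binding protein (0.34, adjusted p = 0.135), Vwf (1.14, adjusted p = 0.227), Wsb1 (0.51, adjusted p = 0.398) and Lrg1 (2.27, adjusted p = 0.398). Heat shock genes had 22 of 23 lower values (median -0.18), and 3 were lower when adjusted over the list alone: Hsph1 at -0.38, Ahsa1 at -0.27 and Stip1 at -0.26 (list adjusted p = 0.356 with an estimated correlation). Immediate early genes had 29 of 35 lower values and 4 called over the list alone, among them Nr4a3 at -0.97 and Dusp6 at -0.41 (adjusted p = 0.356 with an estimated correlation), beside a median of -0.25 for cortex and hippocampus markers. Blood cell genes lay higher, with 6 higher over the list alone (adjusted p = 0.185 with an estimated correlation). Hbb-bs, a haemoglobin chain, averaged 1.18 CPM in controls and 54.2 in stressed mice, and haemoglobin paralogs share reads, so their single values are uncertain. Circadian clock genes had 16 of 18 lower values (adjusted p = 0.356 with an estimated correlation), and glucocorticoid-responsive genes 26 of 33 (adjusted p = 0.515 with an estimated correlation).

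ER chaperone genes on day 7 had 30 of 46 lower values (median -0.08; adjusted p = 0.00144, and 0.515 with an estimated correlation), and that call was also lost without control replicate 2 (adjusted p = 0.0511), control replicate 3 (0.139) or CSDS replicate 3 (0.0757). Hspa5 stood at -0.35, Sdf2l1 at -0.55, Creld2 at -0.14, Xbp1 at -0.13, Atf4 at -0.05, Ddit3 at -0.05, Fkbp5 at -0.02, Tsc22d3 at -0.31, Fos at -0.72 and Npas4 at -0.47 (all adjusted p = 0.999). There were 773 genes at an unadjusted p under 0.05. The Tfrc call was lost when any one of the 6 day 7 libraries was left out, with adjusted p between 0.111 and 0.515 and fold changes between 0.56 and 0.60, and edgeR then called 0 genes in each run. DESeq2 called 9 genes on day 7.

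On day 10, 30 genes were called, of which 9 rose and 21 fell in stressed mice (2310 at an unadjusted p under 0.05). Among those that fell were 3 of the 23 heat shock genes and 4 of the 46 ER chaperone genes, and both list calls were lost with an estimated correlation (adjusted p = 0.383 and 0.637 with an estimated correlation). Hspb1 fell by 1.89 on the log2 scale (SE 0.23, adjusted p = 0.00101), from 15.2 ± 4.8 to 4.10 ± 1.09 CPM (SD, n = 3). The Hsp110 co-chaperone Hsph1 fell by 0.60 (SE 0.10, adjusted p = 0.0149) and the Hsp70-Hsp90 adaptor Stip1 by 0.42 (adjusted p = 0.0499). Of the ER chaperone list, Calr, calreticulin, fell by 0.67 (SE 0.11, adjusted p = 0.0149), the disulphide isomerase Pdia6 by 0.77 (adjusted p = 0.0266), Sdf2l1 by 1.23 (adjusted p = 0.0496) and Hspa5 by 0.96 (SE 0.20, adjusted p = 0.0499). Day 10 controls held 673 to 906 CPM of Calr, above every other library (at most 597). Stressed day 10 libraries, at 451 to 538 CPM, lay within the controls of earlier days (406 to 597). Hspb1 stood at 11.3 to 20.5 CPM in day 10 controls and 6.08 to 13.7 in earlier controls, all above the stressed day 10 libraries (3.02 to 5.21).

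Outside these groups on day 10, Ndn, a growth suppressor of the MAGE family, rose by 1.06 on the log2 scale (SE 0.21, adjusted p = 0.0360), Rbm3, an RNA-binding protein induced by cold, by 0.74 (SE 0.11, adjusted p = 0.0109) and Tfrc by 0.56 (SE 0.09, adjusted p = 0.0149). Other genes that rose were Pla2g4e (1.27), Eml2 (0.39), Deaf1 (0.38), Cntn4 (0.36), Hnrnpdl (0.34) and Exoc2 (0.31). Genes that fell included H2bc6 (-0.99), the G-CSF receptor Csf3r (-0.87), the amino acid transaminase Bcat2 (-0.80), the neuregulin receptor Erbb3 (-0.73), Rbm12b1 (-0.59), Rbm28 (-0.48), Daam2 (-0.48), Lman2l (-0.41), Txnl4a (-0.39) and Rnpep (-0.38). Lars2 (-6.05), LOC118568312 (-7.05) and Gm15564 (-7.30) were also called. Of these, LOC118568312 and Lars2 took 6.03% and 0.841% of the counts of control replicate 1 and at most 0.0939% and 0.0101% of any other library. The values of Lars2 and LOC118568312 therefore came from that library.

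Over the ER chaperone list alone, 16 genes were lower on day 10, among them Derl3 (-1.53), Pdia4 (-0.69), Manf (-0.68) and Hsp90b1 (-0.61), and Cdnf was higher. The list's median was -0.13, with 29 of 46 values below 0 (adjusted p = 3.1e-07, and 0.637 with an estimated correlation). Heat shock genes had 22 of 23 lower values, with a median of -0.37. Of these, 3 were called and 18 were lower when adjusted over the list alone, such as Cryab (-0.94, also on the myelin list) and Chordc1 (-0.63) (list adjusted p = 0.383 with an estimated correlation). Interferon response genes had 27 of 28 lower values, and 5 were lower over the list alone: Bst2 (-1.79), Isg15 (-1.42), Usp18 (-1.36), Irf7 (-1.19) and Rtp4 (-0.72) (adjusted p = 0.490 with an estimated correlation). The list's score was 2.42 to 2.91 in day 10 controls. Stressed day 10 libraries, at 1.95 to 2.29, lay within the controls of earlier days (1.60 to 2.51). On day 1, 26 of 28 interferon response genes had values above 0 (adjusted p = 0.773 with an estimated correlation). Synapse genes had 40 of 41 higher values with a median of 0.14 (adjusted p = 0.730 with an estimated correlation). Immediate early genes had 27 of 35 values above 0 (adjusted p = 0.0272, and 0.885 with an estimated correlation), a call that was also lost without control replicate 1 (adjusted p = 0.628) or CSDS replicate 2 (0.0598). Not passing were Cirbp, also cold-induced (0.58, adjusted p = 0.0628), Creld2 (-0.68, adjusted p = 0.124), Xbp1 (-0.36, adjusted p = 0.220), Ddit3 (-0.18), Atf4 (0.01), Fkbp5 (0.09), Tsc22d3 (0.08), Fos (0.40) and Npas4 (-0.35). Choroid plexus markers, with a median of -1.44, and myelin markers, with 24 of 26 values lower and a median of -0.29 (adjusted p = 0.798 with an estimated correlation), were lower in the same stressed group.

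The day 10 calls depended on single libraries. The count was 12 without control replicate 1, 13 without control replicate 2, 1 without CSDS replicate 1, 12 without CSDS replicate 2 and 1 without CSDS replicate 3. It was 3 with the choroid plexus and cortex scores as covariates (chosen after seeing the data), and edgeR called 0 genes on the day 10 libraries alone (1428 at an unadjusted p under 0.05). Hspb1 stayed called without any one day 10 library. Calr, Rbm3 and Tfrc were lost without CSDS replicate 1 or 3 (adjusted p of up to 0.136, 0.0810 and 0.136). Without control replicate 1, Hspa5 stood at -0.55 (adjusted p = 0.190), Sdf2l1 at -0.89 (adjusted p = 0.202) and Pdia6 at -0.50 (adjusted p = 0.0643), while Calr fell by 0.55 (adjusted p = 0.0484). Over the list alone, 7 ER chaperone genes and 8 heat shock genes were then lower. The Hspa5 and Sdf2l1 calls stayed in 1 of 6 runs each, with adjusted p of up to 0.292 and 0.255, and so did that of Ndn (up to 0.160). Stip1, Pla2g4e, H2bc6, Csf3r, Rbm28, Daam2 and Txnl4a stayed called only without control replicate 3 and Exoc2 only without CSDS replicate 2, while Cntn4, Deaf1, Erbb3 and Hnrnpdl were lost in each of the 6 runs. Hsph1, Pdia6, Rnpep and Lman2l stayed called in 3 of 6 runs and Bcat2, Eml2, Rbm12b1, Lars2, LOC118568312 and Gm15564 in 2.

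Across libraries, with group means removed, the ER chaperone score went with the choroid plexus score (Pearson r = 0.61, Spearman rho = 0.75, n = 24, permutation p = 1e-05 for each, the smallest that the permutations can give; adjusted p = 6e-05 over 6 relations). Without the 2 libraries farthest from the median, day 10 control replicates 1 and 3, r was 0.80.

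**Figure D2:**
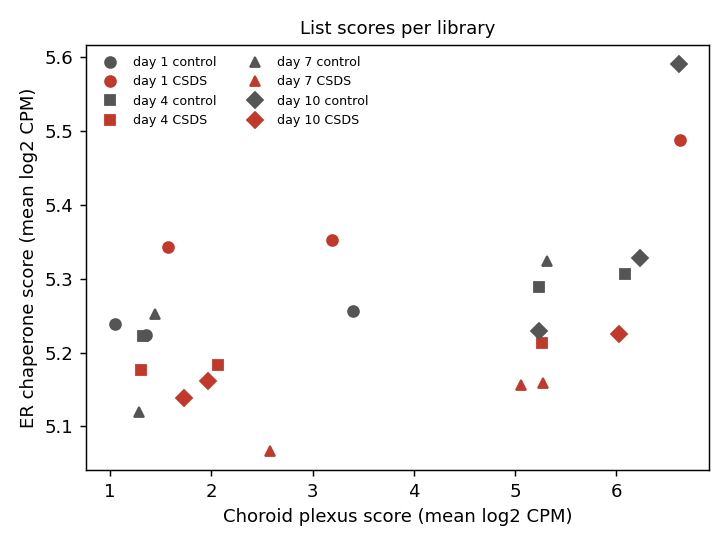
ER chaperone score against choroid plexus score, each the mean log2 CPM of its list, in each of the 24 libraries, with days as symbols and conditions as colours. Choroid plexus scores ran from 1.04 to 6.63 and ER chaperone scores from 5.07 to 5.59.

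**Figure D3:**
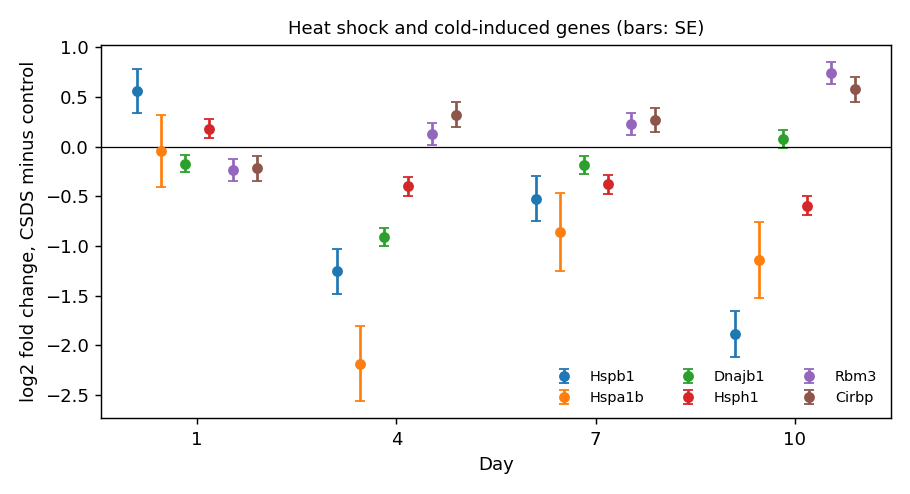
Log2 fold change (CSDS minus control) of 4 heat shock genes and the cold-induced genes Rbm3 and Cirbp on each day; points are edgeR estimates and bars their SE. Hspb1 stood at 0.56 on day 1 and fell by 1.26 on day 4 and by 1.89 on day 10, when Rbm3 rose by 0.74.

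On average over the 4 days, 21 genes were called, 9 higher and 12 lower in stressed mice (1168 at an unadjusted p under 0.05, n = 12 libraries per condition). Ndn rose by 0.93 on the log2 scale (SE 0.10, adjusted p = 1.3e-04), with daily values of 0.94, 0.83, 0.86 and 1.06. Ide, the insulin-degrading enzyme, fell by 0.51 (SE 0.07, adjusted p = 9.9e-04), with daily values of -0.62, -0.61, -0.26 and -0.57. Tfrc rose by 0.40 (SE 0.05, adjusted p = 1.3e-04), although its day 1 value was -0.12. Lrg1 rose by 2.17 (SE 0.25, adjusted p = 1.3e-04), Vwf by 0.86 (SE 0.11, adjusted p = 5.3e-04) and Cxcl12 by 0.24. Further genes with log2 fold changes above 0 on all 4 days were Hbb-bt (2.98), the chemokine Ccl28 (0.57), Slc6a6 (0.19) and Srsf5 (0.18). The day 10 value of Hbb-bt came from CSDS replicate 2 (18.8 CPM). CSDS replicates 1 and 3, at 0.493 and 0.516 CPM, lay below every day 10 control (0.617 to 3.15).

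Lower on average were the heat shock genes Hspa1b (-1.06), Hspa1a (-0.83), Hspb1 (-0.78, adjusted p = 0.00254), Dnajb1 (-0.30, adjusted p = 0.00370) and Hsph1 (-0.30, adjusted p = 0.00779). All 23 heat shock genes had lower values on average, although 17 lay above 0 on day 1, 19 were lower when adjusted over the list alone, and the list's call held with an estimated correlation (adjusted p = 0.0316). Immediate early genes fell too: Egr2 by 0.75 (adjusted p = 0.00779), Fos by 0.73 (adjusted p = 0.0374) and Egr1 by 0.32 (adjusted p = 0.0187), with 32 of 35 values lower, 18 over the list alone, and an adjusted p of 0.0316 with an estimated correlation. These averages include day 1, whose controls held more Egr2 and Fos than the controls of any later day. Atf3, a stress-induced transcription factor, fell by 0.73, Apold1 by 0.37 and Mpzl1 by 0.21. Blood cell genes were higher, 7 of them over the list alone (adjusted p = 0.0847 with an estimated correlation). ER chaperone genes had 31 of 46 lower values (adjusted p = 9.3e-04, and 0.695 with an estimated correlation). The fixed genes that did not pass were Manf (-0.23, adjusted p = 0.559), Hspa5 (-0.30, adjusted p = 0.453), Sdf2l1 (-0.38), Creld2 (-0.15), Xbp1 (-0.07), Ddit3 (-0.07), Atf4 (-0.08), Fkbp5 (0.17), Tsc22d3 (-0.08) and Npas4 (-0.26).

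Ndn, Ide, Tfrc, Lrg1, Vwf, Ccl28, Cxcl12, Srsf5, Hspb1, Dnajb1, Hsph1 and Egr2 stayed called on average whichever of the 24 libraries was left out. Egr1 was lost without day 1 control replicate 2 or day 4 CSDS replicates 2 and 3 (adjusted p of up to 0.0565), and Hspa1b without day 1 control replicate 2, day 1 CSDS replicate 3, day 4 CSDS replicate 2 or day 7 CSDS replicate 3 (up to 0.0556). Fos, Atf3, Apold1, Hspa1a, Slc6a6, Hbb-bt and Mpzl1 stayed called in 5, 3, 3, 7, 7, 6 and 10 of the 24 runs. The count was 13 without day 1 control replicate 2 and 12 without day 4 CSDS replicate 2.

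**Figure D4:**
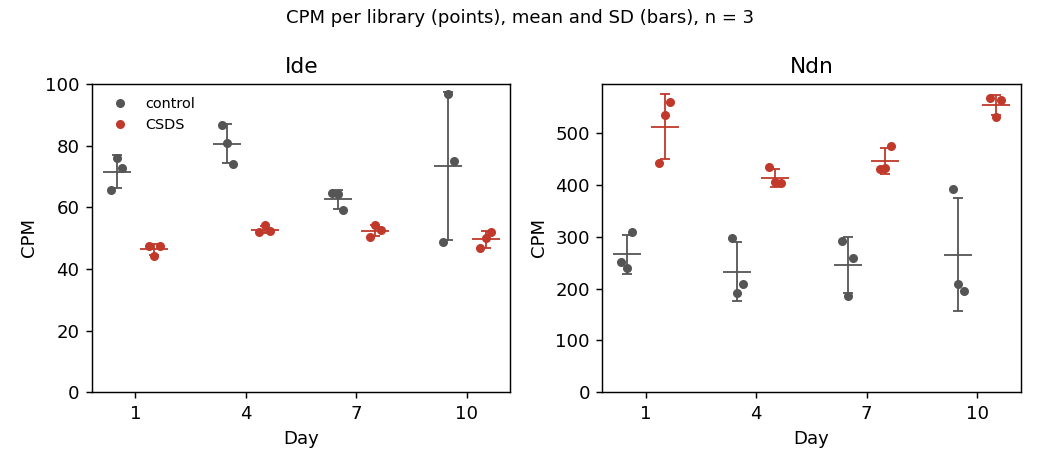
CPM of Ide and Ndn in each library (points) by day, with the mean and SD of each group of 3 (bars); controls are grey and stressed mice red. On average over the 4 days Ide fell by 0.51 and Ndn rose by 0.93 on the log2 scale, and day 10 control replicate 1 held 48.7 CPM of Ide and 391 of Ndn.

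The response to CSDS differed between days for 4 genes (1988 at an unadjusted p under 0.05): Dnajb1 and Hspb1 (both adjusted p = 0.0112), and Hnrnpdl and Egr1 (both adjusted p = 0.0271). Dnajb1 had daily log2 fold changes of -0.17, -0.91, -0.18 and 0.08. Those of Hspb1 were 0.56, -1.26, -0.53 and -1.89, those of Hnrnpdl -0.20, 0.09, 0.34 and 0.34, and those of Egr1 -0.61, -0.74, -0.27 and 0.34. Hspa5 had an adjusted p of 0.137 in this test and Tfrc one of 0.0514. The Hspb1 call held whichever library was left out, Dnajb1 was lost without day 4 CSDS replicate 2 (adjusted p = 0.0651), and the count ranged from 1 without that library to 20 without day 10 control replicate 3. It was 10 without day 4 control replicate 2, day 4 CSDS replicate 3 or day 10 CSDS replicate 2, 11 without day 4 control replicate 3, and 12 without day 7 control replicate 1 or day 10 control replicate 1. Without day 7 control replicate 2, day 7 CSDS replicates 2 or 3, day 10 control replicate 2 or day 10 CSDS replicate 1 it was 2. Egr1 stayed called in 16 and Hnrnpdl in 15 of 24 runs, with adjusted p of up to 0.0903 for either gene.

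Few called genes were shared between days. Tfrc was among the genes that rose on days 4 and 7, on days 4 and 10 and on days 7 and 10, and Hspb1 among those that fell on days 4 and 10 (Fisher's exact test, adjusted p = 0.00299, 0.0179, 0.00299 and 0.0382). Each of these overlaps is of 1 gene. The Tfrc overlaps with day 7 rest on a call that was lost when any one day 7 library was left out (adjusted p of at least 0.111).

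Far more genes differed between days within a condition than between conditions within a day. Among controls 7353 genes (40.7% of those tested) differed between days, and among stressed mice 8650 (47.9%). Zfp638, a zinc finger protein, had the smallest p among controls (adjusted p = 6.4e-10), with differences from day 1 of 0.20, 0.11 and -1.05 on days 4, 7 and 10. Clk1, a splicing kinase, fell by 1.57 from day 1 to day 10 in controls and by 1.73 in stressed mice. The chromatin remodeller Atrx had differences from day 1 of 0.31, 0.31 and -0.73 in controls and of 0.57, 0.52 and -0.60 in stressed mice. Nipbl, Phip, Pcmtd1, Cep290, Zfp62, Zfp942 and Zfp292 in controls had day 10 differences between -1.47 (Zfp942) and -0.49 (Nipbl). Rbm39, Thoc2, Thoc2l and Ccdc88a in stressed mice had day 10 differences of -1.14, -0.64, -1.21 and -0.94. Between days 4 and 7, edgeR called 12 genes among controls and 0 among stressed mice, against between 2991 and 6385 for the other pairs of days. Between days 1 and 4, which lie as far apart as days 4 and 7, 2991 genes were called among controls and 4439 among stressed mice. These counts argue against a steady change with age as the whole cause. Otherwise, day of sampling, age and any batch of library preparation cannot be told apart here, since each day has its own libraries.

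With the preset correlation camera called 15, 16, 17 and 13 of the 32 lists on days 1, 4, 7 and 10 and 10 on average, whereas other splits of the same libraries gave up to 18, 18, 17, 18 and 20 lists. ER to Golgi transport genes had 22 of 27 lower values on day 4 (adjusted p = 0.308 with an estimated correlation), integrated stress response genes 21 of 27 (0.308), ribosomal protein genes 64 of 75 (0.829) and proteasome genes 29 of 31 (0.833). On that day the ribosomal and proteasome scores differed by -0.0765 and -0.0673, and by -0.00945 (95% interval -0.0622 to 0.0433) and -0.0197 (-0.112 to 0.0728) with the trend with gene length removed. On day 10 the same lists lay on the other side, with 60 of 75 and 24 of 31 values above 0 (both adjusted p = 0.949 with an estimated correlation). Their day 10 scores differed by 0.0389 (-0.0756 to 0.153) and 0.0543 (-0.0802 to 0.189). With that trend removed they differed by 0.0655 (0.0127 to 0.118) and 0.0703 (-0.0223 to 0.163), so only the ribosomal interval then lay above 0. For astrocyte markers 17 of 20 values were lower on day 7 (0.457), for oligodendrocyte precursor markers 11 of 15 (0.515), for newborn neuron markers 15 of 22 (0.515), and for cortex or hippocampus markers 16 of 23 (0.442), while inflammation genes had 16 of 24 values above 0 (0.585). All of these p-values are adjusted and with an estimated correlation. Ependyma markers were above 0 in 22 of 22 genes on day 1 (adjusted p = 0.795 with an estimated correlation), and striatum markers in 23 of 24, against 1 of 24 on day 10 (0.795 and 0.885). Mural and leptomeningeal markers were above 0 in 17 of 24 genes on day 4 (0.944). No call was made with the preset correlation, on any day or on average, for ER calcium genes (smallest adjusted p 0.110, day 7), lateral septum neurons (0.197, day 10), medial septum (0.542, day 7), thalamus or hypothalamus (0.115, day 1), microglia (0.183, day 7) or neuropeptides with stress receptors (0.398, day 7). For choroid plexus markers on average, the median and mean were both 0.24 while the test pointed downward (adjusted p = 0.612); no list called with the preset correlation had a median, mean and test of different sign.

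Further lists called with the preset correlation also lay on opposite sides of 0 on different days, and all of the following calls were lost with an estimated correlation. Synapse genes had 31 of 41 lower values on day 1 and 28 of 41 on day 7 (adjusted p = 0.795 and 0.803 with an estimated correlation), against 40 of 41 higher on day 10. Myelin markers were above 0 in 24 of 26 genes on day 1 and mitochondrially encoded genes in 12 of 13 on day 10 (adjusted p = 0.854 and 0.798 with an estimated correlation). Ependyma markers were below 0 in 19 of 22 genes on day 4 and above 0 in 20 of 22 on day 7 (adjusted p = 0.944 and 0.657 with an estimated correlation). Endothelial markers were above 0 in 15 of 20 genes on day 7 and below 0 in 11 of 20 on day 10 (adjusted p = 0.515 and 0.798 with an estimated correlation), and clock genes above 0 in 13 of 18 on day 10 (adjusted p = 0.730 with an estimated correlation).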

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

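The other splits of the libraries and the test of Nnt were set before their results were seen, and the other tests in this part were chosen afterwards. For the heat shock and ER chaperone lists, scores of the whole list replaced earlier tests on counts of called genes and on Hspa5 alone after those values had been seen, and the earlier values are given beside them.

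The response to CSDS differed between days, by the F test of the difference itself, for Dnajb1 and Hspb1 (both adjusted p = 0.0112) and for Hnrnpdl and Egr1 (both adjusted p = 0.0271). Of 100 regroupings of the libraries, 5 splits, the real one included, gave at least these 4 genes and the highest other gave 8, so chance is not excluded for this count.

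For each single day, the 10 splits of 6 libraries are too few for a share under 0.05. The real counts of 1, 20, 1 and 30 genes on days 1, 4, 7 and 10 stood beside highest other counts of 4, 2, 0 and 215, with 2, 1, 1 and 2 splits at least as large, the real one included. The split with 215 genes put day 10 control replicates 1 and 2 and CSDS replicate 2, with 6184 to 8945 CPM of Ttr, against the other day 10 libraries, with 23.6 to 2733. It thus also parted the libraries by choroid plexus RNA, but the cause of its count was not tested. Another split, of day 10 control replicates 1 and 2 and CSDS replicate 3 against the rest, called 24 genes. Its sides overlapped in Ttr (23.6 to 8945 against 37.5 to 6297 CPM). For lists the real counts were 15, 16, 17 and 13 and the highest others 18, 18, 17 and 18, with 4, 3, 2 and 4 splits at least as large. For the average over the days, 1 of 100 splits reached 21 genes, the real one, and the highest other had 2. This argues against chance but does not exclude it, since 1 of 100 is the smallest share that 100 splits can give. Other splits also mix stressed and control libraries, which can raise the spread and lower their counts. For lists on average, 78 of 100 splits gave at least 10, with a highest other of 20, so chance is not excluded. Differences between days among controls (7353, highest other 3398) and among stressed mice (8650, highest other 4463) were reached by 1 split each, the real one. This argues against chance with the same limit, and the many genes in other splits point to the days as a structure that regrouping does not fully remove. The 4 overlaps between days were reached by 1 of 100 splits, the real one, with a highest other of 0, but most other splits call too few genes on a day for any overlap, so this says nothing beyond the gene counts.

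Ide was lower and Ndn higher in stressed mice on all 4 days, by -0.51 and 0.93 on average. Another C57BL/6 substrain, marked by Nnt, which is partly deleted in C57BL/6J, would need a difference of at least 1 in size, and Nnt stood at -0.13 (95% interval -0.24 to -0.03), which argues against it. One unbroken segment from Fgfbp3 to Ide that differs in copy number is argued against by Cpeb3 (0.0531, 95% interval -0.02 to 0.13) and Marchf5 (-0.04, -0.10 to 0.03). Both genes lie between Fgfbp3 and Ide, with values above the Ide interval (-0.66 to -0.37). A copy number difference of the Ide region in some other form stays open, with Fgfbp3 at -0.25 (-0.44 to -0.05) and Btaf1 at -0.31 (-0.45 to -0.18). The median absolute change was 0.117 among 10 other neighbours, some of which lie between Btaf1 and Ide. Noise alone keeps such a median above 0, and their smallest unadjusted p was 0.0708 (edgeR, average), so it cannot decide. A response that builds up over the sessions could not be told apart from a constant one, since the Ide difference between day 10 and day 1 was 0.0579 (-0.35 to 0.47). A response to defeat stays open as untested, and a wrong label of day 10 control replicate 1 stays open too. Over the 12 genes called on day 10 without that library, its median position between the other controls (0) and the stressed libraries (1) was 0.394 (95% interval -0.153 to 1.03). It lay nearer the controls for 6 genes, such as Hspb1 (-0.433) and Tfrc (0.0664), and nearer the stressed libraries for 6, such as Ide (1.03) and Ndn (0.655). These genes were picked by the difference between the other day 10 libraries, which can pull a left-out control above 0. They are also not independent, with Ide and nearby Btaf1 both among them. The interval and these counts therefore cannot decide the label. No stressed day 10 library was out of place for Ide (46.6 to 52.1 CPM).

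Of 23 cytosolic heat shock genes, 22 had values below 0 in stressed mice on each of days 4, 7 and 10, with 4 and 3 called over all genes on days 4 and 10, but the list calls were lost with an estimated correlation (adjusted p = 0.191, 0.356 and 0.383 with an estimated correlation) and the interval of the list score reached 0 on day 7 (-0.22, -0.46 to 0.01), while on day 1 17 values lay above 0 (score 0.105, -0.128 to 0.339; adjusted p = 9.1e-04, and 0.795 with an estimated correlation). Choroid plexus or cortex tissue in the libraries as the whole cause is argued against by the day 10 list score, which was -0.45 (-0.68 to -0.21) before and -0.38 (-0.65 to -0.12) with both marker scores as covariates, and by the earlier count of 15 genes still lower over the list alone (8 genes and a score of -0.28, -0.45 to -0.10, without day 10 control replicate 1 and without covariates). Those covariates enter as a straight line on the log2 scale and may remove tissue RNA only in part, so this does not exclude it. No myelin score was used as a covariate. Gene length bias of the libraries as the whole cause on day 4 is argued against by the day 4 score, which was -0.49 (-0.73 to -0.26) before and -0.47 (-0.69 to -0.25) with each library's trend with gene length removed. A lower temperature of the mice or tissue is a candidate explanation that the data could not decide: the heat shock score and the Rbm3 and Cirbp score had r = -0.20 within groups (permutation p = 0.427, rho = -0.35 with p = 0.176, adjusted p = 0.512 over 6 relations, r = -0.55 without the 2 farthest libraries, n = 24). A response to defeat stays open as untested.

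Of 46 ER chaperone genes, 33 had values above 0 on day 1 and 29 below 0 on day 10 in stressed mice, with 4 called over all genes, on day 10, but the list calls were lost with an estimated correlation (adjusted p = 0.368 and 0.637, and 0.277 for day 10 minus day 1, with an estimated correlation). Day 10 control replicate 1 as the cause of the day 10 part stays open for the list score, which went from -0.21 (-0.36 to -0.06) to -0.10 (-0.22 to 0.01) without it, whereas as the cause for every gene it is argued against by 7 genes lower over the list alone without it, Calr at -0.55 among them (adjusted p = 0.0484 over all genes), and the list's call with the preset correlation stayed (adjusted p = 0.00135). Choroid plexus tissue in the libraries stays open as the whole cause or a part. The ER chaperone score went with choroid plexus markers within groups (r = 0.61). With both marker scores as covariates, day 10 alone stood at -0.13 (-0.27 to 0.01), and day 1 alone went from 0.155 (0.00534 to 0.304) to 0.0983 (-0.0432 to 0.240). The covariates enter as a straight line on the log2 scale and may remove tissue RNA only in part, so what is left cannot decide. The score's difference between day 10 and day 1 was -0.36 (-0.57 to -0.15) before and -0.23 (-0.44 to -0.02) with covariates, so it shrank but stayed below 0. For Hspa5 that difference was -1.44 (-2.02 to -0.86, adjusted p = 0.0213) before and -1.09 (-1.68 to -0.49, adjusted p = 0.265) with covariates, and for Manf -1.11 (-1.60 to -0.61, adjusted p = 0.0400) and -0.84 (-1.36 to -0.32, adjusted p = 0.331), so both calls ended as the fold shrank (without covariates they stayed in 8 and 5 of 12 runs with 1 library left out, those without day 10 control replicate 1 among them, and that of Hspa5 was lost without day 1 control replicates 2 or 3, day 1 CSDS replicate 1 or day 10 CSDS replicate 1, with adjusted p of up to 0.0795). A response to defeat stays open as untested.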

How the results depend on the processing

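The choroid plexus and cortex scores as covariates were chosen after seeing the data, and the other alternatives were planned. For 14 counts there were 249 alternative values: 174 lay within 1.5 times the main count and 75 did not. The counts of genes that differed between days among controls and among stressed mice stayed within 1.5 times under each alternative that gave a value. The replicate block gave none for these. Among named genes, 144 results had 2296 alternative values, of which 18 had the opposite sign and 0 of those were called. The F test results among them have no sign and could not count as opposite. Named genes were not followed under the FPKM, filter or single-day alternatives. Calls were lost in 310 values with 1 library left out, 41 with the replicate block and 19 with covariates. A further 18 were lost with 1 surrogate variable and 5 with RLE size factors. Calls were gained in 3 values with 1 library left out and 11 with DESeq2.

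With DESeq2 the counts on days 1, 4, 7 and 10 were 15, 68, 9 and 112, the average gave 57 and the difference between days 198. With no filter on low counts, day 1 gave 3, day 7 gave 2 and the difference between days 37. RLE size factors gave 0 on day 7 and 13 for the difference between days, and the stricter filter gave 15 for that test. The replicate block gave 0, 10, 0 and 1 on days 1, 4, 7 and 10, 13 on average and 2 for the difference between days. With 1 surrogate variable, day 10 gave 2, the average 33, and 11 lists were called on day 7. FPKM with limma gave 2 for the difference between days at pseudocount 1, and at pseudocount 0.1 it gave 7 there and 0 on day 1. In only that day's libraries, 8, 6 and 0 genes were called on days 4, 7 and 10. With the choroid plexus and cortex scores as covariates the counts on days 1, 4, 7 and 10 were 0, 41, 2 and 3, and 5, 11 and 7 lists were called on days 1, 7 and 10. With the correlation estimated per list, 1, 0, 0 and 0 lists were called on days 1, 4, 7 and 10 and 2 on average. At an unadjusted p under 0.01, 9 overlaps between days passed. Counts of 0 came with 1214 genes at an unadjusted p under 0.05 on day 1 with the replicate block, 1040 with FPKM and 995 with covariates, with 778 (RLE) and 659 (replicate block) on day 7, and with 1428 on day 10 in only that day's libraries. The cause was not tested.

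Leaving out each library in turn (leave-one-out) gave 0 to 1 genes on day 1, 3 to 18 on day 4, 0 to 0 on day 7, 1 to 45 on day 10, 12 to 26 on average and 1 to 20 for the difference between days. Among controls across days it gave 5989 to 7100 genes, among stressed mice 7534 to 8359, and for lists 11 to 18, 11 to 17, 12 to 16 and 10 to 15 on days 1, 4, 7 and 10 and 6 to 13 on average (6 without day 4 CSDS replicate 2). The cause was not tested. The smallest called log2 fold change on day 10 was 0.31 in size. In simulated counts of the same layout a 1.5-fold change on day 10 was called for 41.8% of genes, so a gene without a call is not shown to be unchanged.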

Other observations

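The tests of relations between measures in this part were chosen after the data had been seen. Some clock and glucocorticoid-responsive genes passed only over their own list, while neither list was called on day 1, with 9 of 18 and 19 of 33 values above 0 (adjusted p = 0.666 and 0.665). On day 1, adjusted over the list alone, Npas2 and Per3 were higher by 0.45 and 0.35 in stressed mice while Per1 and Ciart stood at -0.56 and -0.45, and on day 10 Ciart and Cry2 were higher by 0.62 and 0.23, with 13 of 18 clock genes above 0 (list adjusted p = 0.00744, and 0.730 with an estimated correlation). Among glucocorticoid-responsive genes on day 1, Plin4, a lipid droplet protein, was higher by 2.01, Xdh by 0.81 and Fkbp5 by 0.40 over the list alone, with Dusp1 at -0.58 and Errfi1 at -0.28. On day 4, Plin4 was higher by 1.59 and Pla2g3 by 1.12, with Nostrin at -0.92. No gene of this paragraph passed over all genes on these days, and choroid plexus markers had medians of 2.98, -1.28 and -1.44 on days 1, 4 and 10.

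Ide and genes near it on the same chromosome were compared across the 24 libraries with group means removed, as part of 6 relations. Ide against Fgfbp3 had r = 0.76 (permutation p = 0.0177, adjusted p = 0.0357) and rho = 0.47 (permutation p = 0.0706), and Ide against Btaf1 r = 0.86 (permutation p = 0.0178, adjusted p = 0.0357) and rho = 0.56 (permutation p = 0.0394). Without day 10 control replicates 1 and 2 the values of r were 0.38 and 0.49, so much of each relation came from those libraries. Ide against Cpeb3 had r = -0.13 (permutation p = 0.582, adjusted p = 0.582), rho = -0.07 (permutation p = 0.803) and r = 0.26 without the same libraries. Ide against Ndn had r = -0.54 (permutation p = 0.376, adjusted p = 0.512), rho = -0.23 (permutation p = 0.423) and r = 0.02 without them.

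Across the 18060 genes, which are not independent replicates, the log2 fold changes of days 1 and 10 had a Pearson r of -0.35 and a Spearman rho of -0.33, and 37.0% of genes had the same sign. Days 1 and 7 had an r of 0.22, and the other pairs had values between -0.15 and 0.06. Of the 20 choroid plexus markers, 0 belong to another list and 10 reached 1 CPM in every library. The most abundant were Ttr (5.01 to 8945 CPM) and Enpp2 (154 to 4206 CPM). Alb, the serum albumin gene, stood at 30.6, 31.9 and 28.8 CPM in day 10 control replicate 3 and CSDS replicates 1 and 2, and at under 1 CPM in every other library.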
